A study of Mus musculus with 4 samples.

How the data were processed

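Accessible chromatin was measured by NA-seq in 4 samples of sorted FAPs from mdx mice, 1 each of young control, young TSA, old control and old TSA. Per the labels' protocols, the cells were sorted from hind limb muscle as negative for Ter119, CD45, CD31 and α7 integrin and positive for Sca-1, which selects against blood, endothelial and satellite cells. Nuclei were cut with NlaIII or HpaII and the purified DNA was digested further with Sau3AI. Which of the first enzymes was used for which library is not given in the sources used here. An enzyme of this kind reports accessibility only where its recognition site occurs, so regions without sites cannot be called. Per the submitters' processing notes, Bowtie 0.12.7 and the genome build mm9 were used. The region caller, its threshold, the test behind the differential lists, the treatment of reads that align to several places, and any pooling of animals are not given in the sources used here.

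The authors deposited 8 lists of regions, each with only a chromosome, a start and an end. They hold no count, signal, score, fold or p-value. The deposited starts, which count from 0, and the ends are multiples of 100 bp, and the starts printed here count from 1. The shortest region in every list is 1000 bp, and no regions of a list overlap. The most frequent width in the library lists was 1900 bp, from 23.3% of the young control regions to 32.8% of the old control regions. Library size and depth are unknown from these lists, so no value could be weighted by depth, and a region missing from a list is one that was not called, not one shown to be closed. Coordinates were read as mm9 on the submitters' processing notes alone. They were not joined to genes, since the gene table at hand is of another build, GRCm38.

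The sample titles gave the groups, and the treatment field of the controls reads none while the protocol describes saline. Each differential list was taken as higher in the library it was deposited with, and nearly all of its regions overlapped a region called in that library (99.8% for the young lost list, the lowest share of the 4). Gained denotes the list of the TSA library over control and lost that of the control over TSA. Regions were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots were drawn with matplotlib 3.10.9. A region counted as found in another list when it overlapped a region there by at least 1 bp. The shared sequence of a pair is the length covered in both lists over the length covered in either. Exact binomial intervals at 95% treat regions as independent and cover counting error only.

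Each overlap of 2 libraries was set beside 100 random placements of the regions on their own chromosomes, between the lowest start and the highest end of any region there. Assembly gaps and sites of the enzymes were not known, so these placements spread over sequence that could not be called. Overlaps of differential lists between ages and the clustering of differential regions were set beside 100 draws from the merged regions of both libraries of that age. A merged region enters such a draw at most once, while it can hold several differential regions. Recurrence of differential regions in other libraries was also set beside 100 draws from the list of the library they came from, with the same widths (widths of 3000 bp and over counted as 1 class), with replacement. Some differential regions were parts of wider called regions, and the widths of those called regions were not matched. These draws describe the lists and are no tests between animals. Density per Mb uses the span between the lowest start and the highest end called on a chromosome. Regions of the 4 libraries that touched or overlapped were merged for the patterns of calls. The functions were tested on 10 simulated or brute-force cases built on the 97139 old control regions, and the largest difference from the known answer was 1.39%.

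The lists, the comparisons and the alternatives were fixed before the data were examined, except where stated otherwise. The regions named in the text followed a rule fixed in the same way. Without scores and without an mm9 gene annotation, the rule gave the 5 widest regions of each differential list, with ties broken by chromosome and start. The 1 Mb windows, the regions of chromosomes Y and M, those in both lists of an age and the X chromosome were singled out after their values were seen. The alternatives were a reciprocal overlap of 50%, a gap of up to 500 bp counted as shared, the regions at or above the median width of each list, autosomes only, lists thinned at random to the length of the shortest, and regions closer than 1 kb merged. For the differential lists they were regions called in 1 library only and covered length. Leaving out replicates, blocking and splits of the samples need more than 1 library per group. The planned analyses of gene annotation, of fixed gene lists, of enzyme sites, of sequence motifs and of region scores were not run, since they need an mm9 genome, an mm9 annotation or scores, which were not used here. The width-matched draws were chosen after seeing the data.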

Results

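Chromatin accessibility was profiled in fibro/adipogenic progenitors (FAPs) from the hind limb muscles of mdx mice. FAPs are mesenchymal cells that lie between muscle fibres, support their repair and can become fibroblasts or fat cells. The mdx strain lacks dystrophin and is a mouse model of Duchenne muscular dystrophy. Young and old mice had received daily injections of trichostatin A (TSA), an inhibitor of histone deacetylases, or of saline, for 15 days, with TSA at 0.5 mg per kg per day. The libraries were made by NA-seq, in which a restriction enzyme cuts the DNA of intact nuclei where the chromatin is open. The 4 samples were 1 young control, 1 young TSA, 1 old control and 1 old TSA library. The deposited lists give the regions that the authors called as accessible in each library, and for each age the regions that differed between TSA and control. With 1 library per group there was no replicate, so no difference between libraries has an error between animals and no p-value was computed. The lists hold no read counts, scores or heights, so the sequencing depth behind each region is unknown. Intervals given below are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only. All coordinates are of the mouse build mm9.

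The first comparison asked how TSA altered accessibility in FAPs of young mdx mice. The young TSA library held 80122 accessible regions against 43335 in the young control library, a ratio of 1.85. The regions covered 141 Mb after TSA and 67.9 Mb in the control. Of the regions that the authors listed as differing, 8362 were higher in the TSA library (gained) and 468 were higher in the control (lost). Gained regions were thus 94.7% of the 8830 differential regions (interval 94.2 to 95.2%). They covered 13.2 Mb against 0.638 Mb for the lost regions. Of the gained regions, 28.9% (28.0 to 29.9%) also overlapped a region called in the young control, and the remaining 5943 had no called region there. Young TSA regions drawn to the same widths overlapped the young control in 25.7% of cases (24.2 to 26.6% over 100 draws), and all young TSA regions in 30.6%. The gained regions were thus called in the control more often than the draws and slightly less often than the whole young TSA list. Of the lost regions, 17.5% (14.2 to 21.3%) overlapped a region called after TSA, against 49.3% for young control regions of the same widths.

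The widest gained regions of the young mice lay on chromosomes 10, 11 and 12. The widest, chromosome 10 from 74398101 to 74405300, spanned 7200 bp. It was called in young TSA, old control and old TSA but not in the young control, and it overlapped the gained list of the old mice as well. The region on chromosome 10 from 58756601 to 58761800 had the same pattern of calls but overlapped the lost list of the old mice. A further region of that chromosome, from 80704801 to 80709600, was also called in every library except the young control and was in neither old differential list. The regions on chromosome 12 from 109543901 to 109549900 and on chromosome 11 from 74978901 to 74983700 were called in all 4 libraries. Among the lost regions, 4 of the 5 widest fell on chromosome 11 between 3059601 and 3098300, and the other on chromosome Y from 2782201 to 2784800. These 5 regions overlapped called regions in all 4 libraries, and 3 of them also overlapped the gained list of the same mice. Which genes lie at these positions is not analysed here.

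Of the young control regions, 57.0% (56.6 to 57.5%) overlapped a young TSA region. The same regions placed at random on their chromosomes overlapped in 10.7% of cases on average over 100 placements. From the other side, 30.6% (30.3 to 30.9%) of the young TSA regions overlapped a young control region, against 5.87% when placed at random. The shared sequence was 22.1% of the sequence covered in either library. Gained regions lay close to each other more often than regions drawn from all those called in the young libraries. Of the gained regions, 49.8% had another gained region within 50 kb, against 40.7% in 100 draws (39.0 to 42.1%). The corresponding share of the lost regions was 7.91%, against 0.427 to 5.77% in the draws. A called region can hold several differential regions but enters a draw only once, so the draws understate closeness by construction. The window of chromosome 11 between 3 and 4 Mb held 11 of the lost regions. Without it the share within 50 kb was 5.69%, below the highest draw of 6.13%, and that within 10 kb was 2.41%, above the highest draw of 2.19%.

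**Figure D1:**
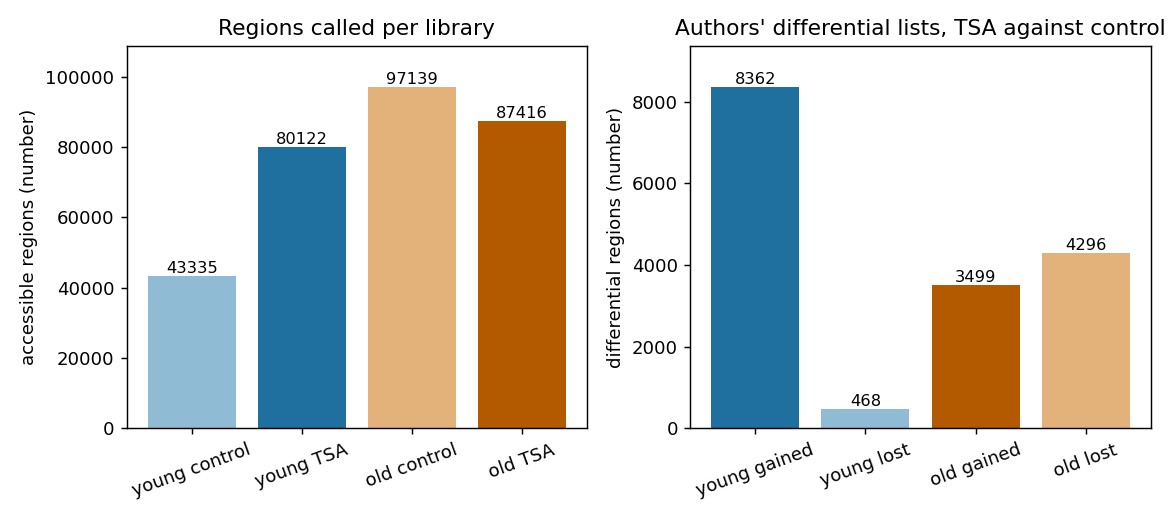
Bars give the number of accessible regions called in each library (left) and the number of regions in the authors' differential lists (right), on linear axes that start at 0. Young TSA held 80122 regions against 43335 in the young control, while old TSA held 87416 against 97139 in the old control, and gained regions outnumbered lost regions only in the young mice.

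The same comparison in old mdx mice gave differences in both directions. The old TSA library held 87416 regions against 97139 in the old control, a ratio of 0.900. The authors listed 3499 gained and 4296 lost regions, so that gained regions were 44.9% of the 7795 differential regions (43.8 to 46.0%). Gained regions covered 4.68 Mb and lost regions 5.97 Mb. Of the gained regions, 23.0% (21.6 to 24.5%) overlapped a region of the old control, and of the lost regions 24.4% (23.2 to 25.8%) overlapped a region of old TSA. For regions of the same widths drawn from old TSA and old control, these shares were 41.5% and 37.0%. Whether the response to TSA differed between the ages could not be tested, because each age and treatment is represented by 1 library.

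The widest gained region of the old mice lay in the mitochondrial genome, from 3201 to 7000. It was called in all 4 libraries and was also in the gained list of the young mice. As it lies outside the nucleus, it is no measure of nuclear chromatin. A gained region of 2700 bp on chromosome 9 from 67858201 to 67860900 was called in old TSA alone among the 4 libraries. Those on chromosome 12 from 56540901 to 56543300 and on chromosome 14 from 26256701 to 26259100 were called in old TSA and young TSA but in neither control. The gained region on chromosome 17 from 39982201 to 39984600 was called in all 4 libraries and was gained at both ages. Among the lost regions, the widest lay on chromosome 16 from 8843101 to 8846300. It was called in old control and young TSA and belonged to the gained list of the young mice. The lost regions on chromosome 9 from 74354001 to 74356900, on chromosome 11 from 117865101 to 117867900 and on chromosome 15 from 93315801 to 93318500 were called in old control alone. The lost region on chromosome 13 from 109083101 to 109086100 was called in all 4 libraries.

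Old control and old TSA overlapped in 49.3% (49.0 to 49.6%) of the old control regions and in 54.8% (54.5 to 55.2%) of the old TSA regions. Random placement gave 11.9% and 13.2%. The shared sequence was 32.4% of the sequence covered in either library. Of the gained regions, 20.9% had another within 50 kb, against 17.2% in draws from the called regions (15.2 to 18.9%). Within 10 kb the share of 4.77% lay within the range of the draws (3.14 to 5.54%). For the lost regions the share of 21.0% lay within the range of the draws (18.4 to 22.2%).

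Few differential regions were shared between the ages. Of the 8362 young gained regions, 291 (3.48%, 3.10 to 3.90%) overlapped a region gained in the old mice. A larger number, 393 (4.70%, 4.26 to 5.18%), overlapped a region lost in the old mice. Equal numbers of regions drawn from all those called in the young libraries overlapped the old gained list in 1.81% (1.45 to 2.26%) and the old lost list in 1.86% (1.51 to 2.16%). Both overlaps of the young gained list were therefore above every draw. These draws were not restricted to regions called in the old mice. Young gained regions were called there more often than width-matched young TSA regions (77.6% against 52.1% in the old control). That recurrence can by itself raise the overlap with either old list, so the excess does not show that the same regions responded at both ages. From the old side, 8.23% of the old gained and 9.17% of the old lost regions overlapped a young gained region. Of the 468 young lost regions, 5 overlapped a region gained and 3 a region lost in the old mice, both within the range of the draws.

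Most regions gained with TSA in young mice were also accessible in old mice, with and without TSA. Of the 8362 regions, 77.6% (76.6 to 78.4%) overlapped a region of the old control and 77.4% (76.5 to 78.3%) a region of old TSA. In both old libraries together 5640 of them (67.4%) had a called region, and in neither old library 1042 (12.5%). The whole young TSA list overlapped the old control in 56.6% of its regions. Young TSA regions drawn to the same widths overlapped it in 52.1% (51.0 to 53.2% over 100 draws). Regions lost in young mice showed the opposite difference. Of these, 24.8% (20.9 to 29.0%) were called in the old control and 23.5% (19.7 to 27.6%) in old TSA, against 45.6% and 46.0% for young control regions of the same widths. Such draws overlapped young TSA in 49.3% of cases, against 17.5% of the lost regions. They therefore do not separate lost regions from other young control regions that were not called in young TSA.

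The differential regions of the old mice were set beside such draws in the young libraries. Of the old gained regions, 45.8% (44.1 to 47.5%) were called in young TSA, against 37.8% for old TSA regions of the same widths (36.0 to 39.9%). In the young control they were called in 21.3% of cases against 17.5%. The whole old TSA list overlapped young TSA in 52.0% and the young control in 25.9% of its regions, above the values of the old gained regions. Of the old lost regions, 39.0% (37.6 to 40.5%) were called in young TSA against 34.8% in the draws (33.1 to 36.8%). In the young control the old lost regions were called in 14.1% (13.0 to 15.1%) of cases, and the draws gave 16.3% (14.9 to 17.8%). The whole old control list overlapped young TSA in 46.8% and the young control in 22.9% of its regions, above the values of the old lost regions. The excess in young TSA thus holds against the width-matched draws only.

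**Figure D2:**
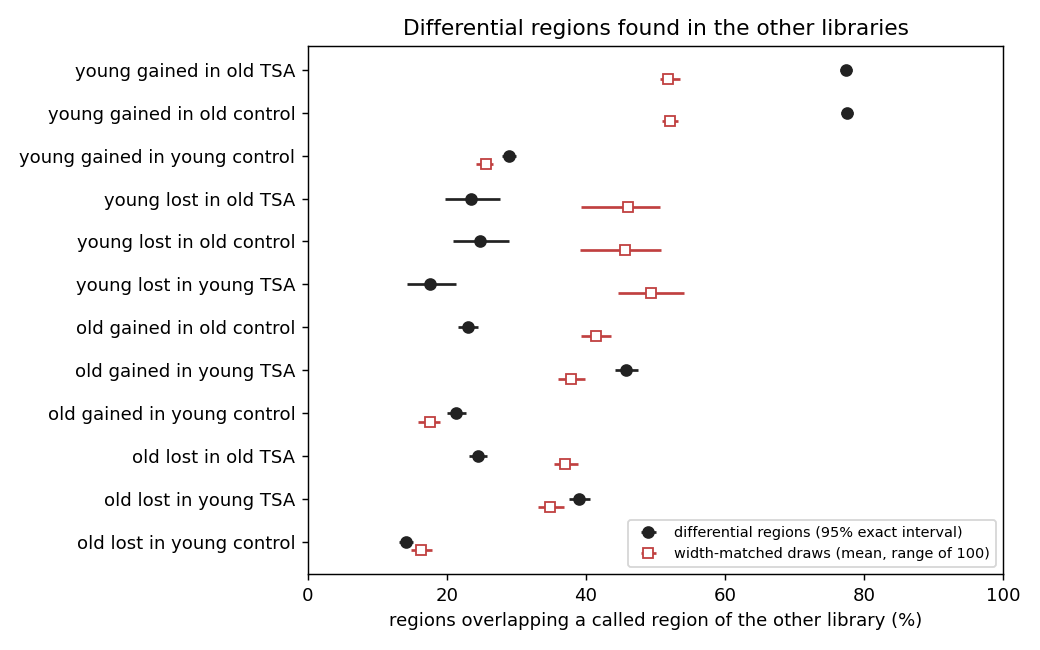
Filled points give the share (%) of each authors' differential list that overlapped a called region of another library, with 95% exact binomial intervals, and open squares the mean and range of 100 draws of the same widths from the library in which the differential regions were higher. Young gained regions were found in the old control in 77.6% of cases against 52.1% in the draws, and young lost regions in 24.8% against 45.6%. The draws were not matched on calls in the other library of the same age.

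Without TSA, the libraries of the 2 ages differed in the number of regions, with 97139 in the old control and 43335 in the young control. Of the young control regions, 51.5% (51.0 to 52.0%) overlapped an old control region, against 12.7% at random. Of the old control regions, 22.9% (22.6 to 23.2%) overlapped a young control region, against 5.73% at random. The shared sequence was 15.9% of that covered in either control. With TSA the ages had more in common. Young TSA and old TSA held 80122 and 87416 regions, which overlapped in 56.6% (56.3 to 57.0%) of the young and 52.0% (51.7 to 52.4%) of the old regions. Their shared sequence was 34.8% of that covered in either, the highest value of the 6 pairs of libraries. Young TSA shared 31.6% with the old control and 22.1% with its own control. These values depend on the lengths of the lists. With every list thinned at random to 43335 regions, which lowers the overlaps by construction, the young control overlapped young TSA in 31.0% and the old control in 23.1% of its regions, and young TSA overlapped old TSA in 28.3%.

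Merging the 4 lists gave 167247 regions. Of these, 87908 (52.6%) were called in 1 library only, 38227 (22.9%) in 2, 26359 (15.8%) in 3 and 14753 (8.82%) in all 4. The most frequent pattern among those shared by 3 libraries was absence from the young control, with 17950 regions. Absence from old control alone was found for 3332 regions, from old TSA alone for 2836 and from young TSA alone for 2241. Of the 32703 regions that the other 3 libraries shared, the young control thus lacked 54.9% (54.3 to 55.4%). The corresponding shares were 18.4% for old control, 16.1% for old TSA and 13.2% for young TSA. A shorter list lacks more regions by itself. With every list thinned at random to 43335 regions, so that only the young control kept all of its regions, the shares were 53.8% for young control, 61.8% for old control, 56.4% for old TSA and 50.7% for young TSA. Thinning raises the shares of the other libraries by construction. It does not show how much of the young control share stems from list length. Regions called in 1 library had median widths of 1300 to 1400 bp, and those called in all 4 had a median merged width of 2500 bp.

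The chromosomes carried regions at unequal density. Among the autosomes, chromosome 14 had the lowest density in all 4 libraries, from 13.9 regions per Mb in the young control to 33.3 in the old control. The highest density lay on chromosome 11 in both young libraries, at 23.2 and 41.9 regions per Mb in control and TSA. In the old control it lay on chromosome 5 (44.8 per Mb) and in old TSA on chromosome 7 (41.6 per Mb). The X chromosome had a lower density than every autosome in each library, and the gap differed with age. It held 412 regions in the young control, 727 in young TSA, 1991 in the old control and 1510 in old TSA. These were 0.951% (0.862 to 1.05%), 0.907% (0.843 to 0.975%), 2.05% (1.96 to 2.14%) and 1.73% (1.64 to 1.82%) of the regions of each library. Relative to the mean density of the autosomes, the X chromosome stood at 0.142 and 0.135 in the young control and TSA libraries and at 0.309 and 0.260 in the old ones. The sex of the mice is not given in the labels. Among the differential lists, the X chromosome held 53 young gained regions, or 0.634% of that list (0.475 to 0.828%), below its 0.923% of the called regions of the young libraries. The other lists did not differ from the called regions beyond counting error. The X chromosome held 7 young lost regions (interval 0.603 to 3.06% of that list), and in the old mice 51 gained (1.46%, 1.09 to 1.91%) and 83 lost regions (1.93%, 1.54 to 2.39%), where its share of the called regions was 1.90%. Chromosome Y held 17, 18, 17 and 15 regions in young control, young TSA, old control and old TSA.

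**Figure D3:**
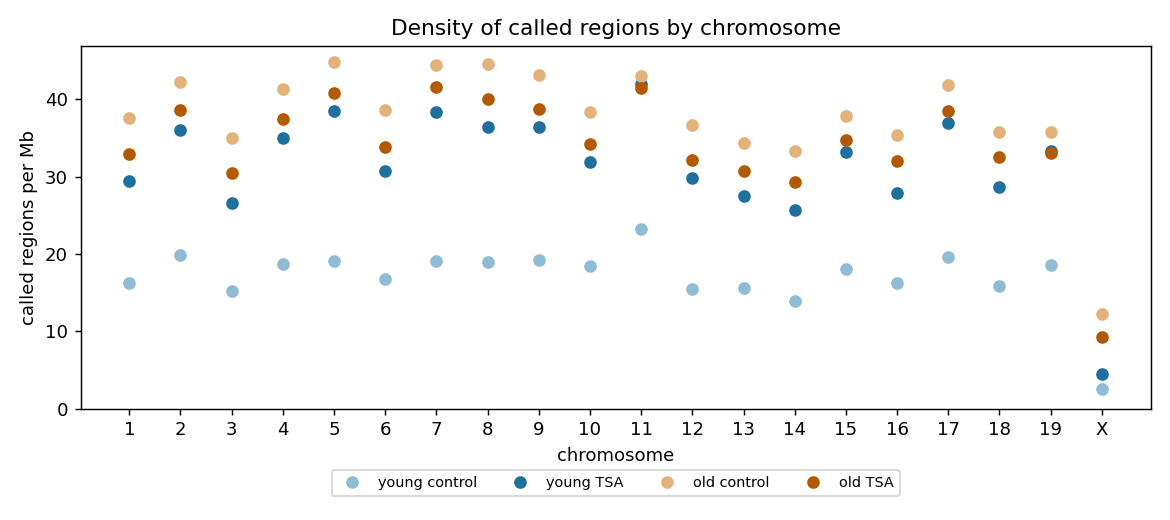
Points give the number of called regions per Mb of each autosome and of the X chromosome in the 4 libraries, on a linear axis that starts at 0. The X chromosome lies below every autosome, at 2.52 and 4.45 regions per Mb in the young control and young TSA libraries and at 12.2 and 9.25 in the old control and old TSA libraries.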

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

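The tests on regions of 1900 bp or wider, on the wider regions of each list and on regions missing from 1 library were chosen after the result was seen. The TSA library held more regions than its control in young mice (log2 ratio 0.89) and fewer in old mice (log2 ratio -0.15). In the authors' differential lists the gained share was 94.7% in young and 44.9% in old mice. Counting instead the regions called in only 1 library of that age, the TSA share was 74.9% in young and 44.5% in old mice. These results stand out because the TSA and control libraries differed in opposite directions at the 2 ages. The difference was not tested, since each age and treatment has 1 library.

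Regions near the calling limit and a less sensitive young control library both stay open, as does a true difference of the young untreated cells. Among regions of 1900 bp or wider, the ratio of TSA to control was 2.82 in young and 0.854 in old mice, farther from 1 than for all regions. Young control regions were also narrower (median 1500 bp, against 1800 bp after TSA), so the ratio does not separate weakly called regions from a response to TSA. The young control lacked 54.9% of the regions that the other 3 libraries shared, against at most 18.4% for any other library, and 57.9% against at most 20.1% among the wider regions of each list. With lists thinned to equal length the share was 53.8% for young control and 50.7 to 61.8% for the others, which thinning raises by construction. A shorter list lacks more regions by itself, and a less sensitive library and a true difference would both give a shorter list. Without read depths these explanations cannot be told apart, and age was not separated from differences between animals or library preparations.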

How the results depend on the processing

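Altogether, 169 alternative values were computed for 47 results. Of these, 57 stayed within the counting interval of the reported value (or within 1.5 times for a number of regions), and 112 moved beyond it; with so many regions that interval is narrow. Only 22 of the values belong to results with a direction (TSA to control ratios, gained shares and clustering ratios), and none of the 22 changed it, although the old gained clustering within 10 kb (4.77%) no longer exceeded the highest draw (5.54%). The alternatives restricted to regions of 1900 bp or wider, to differential regions without a called region in the other library, to 3 libraries, the patterns at equal list length and the width-matched draws were chosen after seeing the data. The ratio of young TSA to young control regions was 1.78 with regions closer than 1 kb merged, 2.08 by covered length and 2.82 for regions of 1900 bp or wider, where the old ratio was 0.854. The gained share in young mice was 74.9% from regions called in 1 library only, 95.4% by covered length, 97.5% in the wider regions and 93.9% without a called region in the other library. In old mice it was 42.4% in the wider regions. For the overlaps of young control with young TSA, old control with old TSA, young control with old control, and young TSA with old TSA, a reciprocal overlap of 50% gave 48.6%, 44.4%, 42.9% and 51.2%, and a gap of 500 bp gave 59.1%, 51.4%, 54.0% and 58.8%. Random thinning to equal length gave 31.0%, 24.7%, 23.1% and 28.3%, lower by construction since regions were removed. Thinning also gave shares of regions missing from young control, young TSA, old control and old TSA of 53.8%, 50.7%, 61.8% and 56.4%, again shaped by construction, as only the young control kept all its regions. In the wider regions (at or above the median width) the overlap was 48.5% for old control with old TSA. It was 46.8% for young control with old control and 55.6% for young TSA with old TSA. With near regions merged these 3 overlaps were 50.1%, 52.0% and 57.7%. The old pair was 49.7% on autosomes. Young gained regions overlapped the old gained list in 2.30% (reciprocal), 3.96% (gap of 500 bp) and 2.62% (wider regions), and the old lost list in 3.67% (reciprocal) and 4.07% (wider regions). They were found in the old control in 64.0% (reciprocal) and 79.2% (gap of 500 bp) of cases, where width-matched draws gave 47.0% and 54.7%. Regions in all libraries were 9.53% with regions within 500 bp merged, 8.17% in the wider regions, 1.63% at equal length and 20.9% with the young control left out. Apart from the thinning, the cause of these shifts was not tested. Alternatives on gene annotation, gene lists, enzyme sites, motifs and ranking by score were not run. Leaving out replicates was not possible with 1 library per group. No paired analysis was possible because each group has 1 library and no comparison rests on a test. The unknown depth limits every statement on regions absent from a list.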

Other observations

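The tests of explanations, the neighbour counts and the 1 Mb windows in this part were chosen after the results were seen. The young gained regions were concentrated where many regions were called. Around a young gained region, the median number of young TSA regions within 500 kb was 55, against 46.9 on average for young TSA regions of the same widths (46 to 48 over 100 draws). For the young lost regions the median number of young control regions was 21, against 25.4 (23 to 27). The corresponding values were 49 against 43.7 for the old gained and 49 against 46.5 for the old lost regions. The 1 Mb windows of mm9 with most young gained regions lay on chromosome 10 from 79 to 80 Mb (34 regions) and from 80 to 81 Mb (33 regions). They were followed by chromosome 8 from 124 to 125 Mb (31 regions) and from 123 to 124 Mb (24 regions), and by chromosome 4 from 154 to 155 Mb (23 regions), where an average window held 3.25. The window from 123 to 124 Mb of chromosome 8 was also among the 5 with most old gained regions, with 10.

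Some positions appeared in both differential lists of the same age. In each age, 14 lost regions overlapped a gained region, and 3 of the young ones lay on chromosome Y. The stretch of chromosome 11 near 3.1 Mb held the widest called region of the young control (44500 bp, from 3056401 to 3100900). The young lost region from 3093301 to 3098300 in that stretch overlapped the young gained list and both lists of the old mice. In the mitochondrial genome, 3 gained regions were listed in young and 2 in old mice, and no lost region in either. These calls lie outside the nucleus and are no measure of nuclear chromatin.

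The high recurrence of young gained regions in the old mice was a pattern found in these data. The hypothesis that wide regions recur in any library was tested by drawing young TSA regions of the same widths, which overlapped the old control in 52.1% of cases, at most 53.2%, against 77.6% for the gained regions. Widths were matched to the gained regions as listed, which can be parts of wider called regions. The draws therefore do not exclude an effect of the width of the called regions. The hypothesis that the young control missed regions at random was tested on the 5943 gained regions without a young control region. Of these, 71.4% were called in the old control, against 48.3% (at most 50.9%) for young TSA regions of the same widths that the young control also lacked. This does not exclude such misses, since a differential list may select strong regions, which recur for that reason and could not be matched without scores, and it also stays open that TSA in young mice may open regions already open in old mice.

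The larger X share of the old libraries was present with and without TSA. A longer list is not a sufficient explanation: the X share of old TSA was 1.90 times that of young TSA, while old TSA held 1.08 times as many autosomal regions. A candidate explanation is that the old libraries came from female mice and the young ones from male mice, as the labels give no sex. Of 19 merged regions on chromosome Y, 12 were called in all 4 libraries, 2 in both young and no old library and 1 in both old and no young library. The Y calls cannot decide this, since those positions may hold sequence repeated on other chromosomes. That could not be checked without the genome sequence, and age and any batch of the young and old libraries remain open as well.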
